A study of Caenorhabditis elegans with 2 samples.

How the data were processed

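Chromatin immunoprecipitation and sequencing was carried out on whole late embryos of C. elegans strain OP315, 5 hours after egg bleaching, per the labels. The 2 biological replicates carry their numbers in the labels and form 1 group. Both were used, and no sample of another group or control library was analysed here. Worms carried CEH-14 with a C-terminal GFP-FLAG tag, and chromatin was sonicated and precipitated with an anti-GFP antibody, per the labels. That the replicates are biological is the labels' statement.

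The files are narrowPeak lists in the ce10 and ce11 assemblies: the IDR peaks and a pooled relaxed list for both replicates together, and a relaxed list per replicate. Per the sample records deposited beside them, the relaxed lists derive from the alignments of a replicate, or of both, and from 1 further file whose kind they do not state, and the IDR peaks derive from the relaxed lists. The labels name a possible control experiment, which was not analysed here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each entry is the authors' own, on a scale of its own in each list, and was used only to rank, describe and filter peaks within a list. The deposited −log10 q-value column was capped at 1 highest value within each list, which 1681 of 1681 IDR peaks reached, so it was not used to rank. The deposited p-value and score columns hold a constant and were not used. The lists give no read numbers, so depth is unknown and precision rests on the number of entries; intervals given for shares cover counting error only.

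Only the ce11 lists were used with coordinates, since ce11 and the WBcel235 assembly are the same sequence: the highest entry end on each chromosome did not pass the reference length. Gene models were those of Ensembl release 115, and sequence was the RefSeq copy of the same assembly. All coordinates are 1-based. The ce10 list was compared by number, chromosome and signal value, and coordinates were not converted.

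Tests, gene lists, window sizes and hexamers were fixed before the data were examined. A gene counted as having a peak when a summit lay within 1000 bases of an annotated transcript start. Summits were placed at random 1000 times on their own chromosome, one-sided for the share near starts and two-sided for annotation classes, with classes exclusive in the order coding exon, untranslated region, exon of a non-coding gene, intron, 1000 bases upstream, other intergenic. Chromosome shares were tested with the exact binomial test, two-sided, with each autosome split into outer and middle parts so that the outer parts hold 66.7% of the sequence. Gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, adjusted by Benjamini-Hochberg over 29 lists at a threshold of 0.05. Of the lists' symbols, 7 were not matched to a protein-coding gene of the annotation and were left out: ceh-35, ceh-44, ceh-85, opt-2, mir-228, efn-1 and daf-21. Hexamers on both strands were tested with McNemar's exact test for presence within 50 bases of the summit against 2 flanks of the same total length centred 300 bases away, adjusted over 2080 hexamers. The comparison of TAATTA with other hexamers made of A and T alone was chosen after the data were seen. Medians were compared by permutation with 100000 resamples, two-sided, with bootstrap intervals from 2000 draws at 95%. Entries of 2 lists matched when each covered at least 50% of the other. Ranks of named peaks in the replicates come from the strongest overlapping entry, except for the peaks that differ most in rank.

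Genes were named by a rule fixed beforehand: ceh-14; protein-coding genes within 1000 bases of the 20 strongest summits, or else the nearest; up to 5 members with the strongest peaks in each gene list; members of lists with 20 or fewer genes that have no peak; the genes with the most peaks within 5000 bases upstream or in the gene body; and the peaks that differ most in rank between replicates.

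The procedures were tested on simulated data. With 19985 genes, 94.0% of lists raised 5-fold were called, and 0.091% of unchanged lists. The raised lists were those of 78 ribosomal protein, 32 epidermis and 269 nuclear hormone receptor genes. The 94.0% therefore does not cover smaller lists, such as the 7 LIM homeobox genes. Simulated genes were drawn independently, whereas in the data neighbouring genes can share a summit and genes differ in their number of starts. The 0.091% may therefore not carry over to the data. With 1681 summits, TAATTA added to 8% of centres was called in 100% of simulated sets, with a mean of 0.2 unchanged hexamers called per set. These summits were random nuclear positions. The IDR summits had 47.8% GC against 36.1% in their flanks, so these rates may not carry over to them. With 1681 summits, random summits gave a p below 0.05 in 4.0% of sets, and 90.0% of sets passed when 8% of summits were moved to starts. In simulated sets of 400 values, the permutation of medians passed in 0% of unchanged and 100% of raised sets, and all 1681 entries shifted by 20 bases matched.

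Alternatives were the stronger 840 peaks, each replicate's strongest entries alone, merged overlapping entries, windows of 500 and 2000 bases, protein-coding genes only, the single nearest start, 5000 bases upstream or the gene body, a background of genes with a pooled entry, upstream length as a covariate in logistic regression, hexamer windows of 25 and 100 bases, pooled entries outside the IDR peaks as comparison, and other rules for matching replicates. The logistic regression could be fitted for the 18 lists with a peak and was adjusted over those, where collagen and nuclear hormone receptor genes passed besides the 4 lists past the threshold without the covariate; adjusted over all 29 lists, only these 4 passed. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.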

Results

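CEH-14 is a LIM homeobox protein, a DNA-binding protein known for its part in the identity of several C. elegans neurons, among them the AFD thermosensory neurons and the ALA and BDU neurons. The study mapped where a tagged form of it was recovered on the genome of whole late embryos, 5 hours after eggs were released by bleaching. The worms, of strain OP315, carried CEH-14 with a GFP-FLAG tag at its C-terminus. Chromatin was sheared by sonication and precipitated with an antibody against GFP. A further label gives the antibody's target as CEH-14, the tagged protein. The series holds 1 group, CEH-14-GFP late embryos, with 2 biological replicates, and no control library among the samples. No comparison between groups was therefore possible, and the account below describes the peaks, how far the replicates shared them, and where they lay.

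The authors' list of peaks kept by the irreproducible discovery rate (IDR, a measure of how well 2 replicates rank the same peaks) held 1681 peaks in ce11 coordinates. The peaks were 114 to 593 bases wide, with a median of 456 bases, and covered 702349 bases or 0.700% of the genome. Chromosome X held 324 peaks, I held 311, III held 294, II held 264, IV held 251, V held 227 and the mitochondrial genome held 10. The authors' signal value, which ranks peaks within a list, ran from 72.97 to 1479.9 with a median of 102.8. The relaxed lists, which hold background regions as well as peaks, had 21217 entries for replicate 1, 19577 for replicate 2 and 21766 for both replicates pooled. The 1681 IDR peaks were exactly the 1681 strongest entries of the pooled list. Not every one had an entry in both replicates. By at least 1 base, 1672 overlapped an entry of replicate 1 and 1680 an entry of replicate 2. The ce10 list of the same experiment held 1699 peaks, and 1666 of the ce11 peaks had a ce10 peak on their chromosome with a signal value within 0.1%. Read numbers are not given in these lists, so the depth behind a peak is unknown.

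The strongest peak of the experiment lay on chromosome III at 8043714 to 8044196, upstream of K12H4.5 and 531 bases from its start, with a signal value of 1479.9. It ranked first in both replicates, with signal values of 720.3 and 761.5. The peak that ranked second in the pooled list, on III at 3499827 to 3500219, lay in an intron and was 977 bases from the start of M01F1.9. Upstream of eel-1, which encodes a HECT-type ubiquitin ligase, 2 overlapping peaks on IV ranked 6 and 17. Other peaks among the 20 strongest lay 30 bases from the start of ears-2 and 62 from that of uncp-18, 62 bases from the start of atx-2 and 776 from that of ecps-1, and 55 bases from the start of tasp-1 and 730 from that of K01G5.10. The peak upstream of the ribosomal protein gene rpl-3 (III, 3867431 to 3867741) had a signal value of 449.3, and the peak shared by idhg-1 and mlcd-1 had 438.8. Some of the 20 strongest had no protein-coding start within 1000 bases: for these the nearest were those of W03C9.1 (1294 bases), pxn-1 (5659 bases, summit in its intron), F55C5.17 (1098 bases), cutl-18 (2688 bases, summit in its intron), T06A4.1 (15103 bases) and str-56 (1380 bases). All of these peaks except the one nearest T06A4.1 had a snoRNA gene within 200 bases of the summit, as named further below. The genes with the most peaks within 5000 bases upstream or in the gene body were gpb-1, which encodes a G protein beta subunit, ppfr-1, and the mitochondrial COX3 and WBGene00010964, with 6 peaks each.

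How many of their strongest entries the replicates shared depended on the matching rule. The IDR peaks derive from these same lists, so that finding them there is a description and no test of agreement. At a reciprocal overlap of 50%, 1556 IDR peaks (92.6%) were met in the relaxed list of replicate 1, 1571 (93.5%) in that of replicate 2 and 1539 (91.6%) in both. The 93 met in neither were narrow, with a median width of 158 bases, and all 93 overlapped entries of both replicates by at least 1 base. Of the 1681 strongest entries of replicate 1, 1146 (68.2%, Wilson 95% interval 65.9 to 70.4%) matched 1 of the 1681 strongest of replicate 2, and 806 (47.9%) did when summits had to lie within 50 bases. Across the peaks met in both lists, Spearman's rho of the signal values was 0.527, a description across peaks, which are not independent replicates. The peaks that differed most in rank were those near hst-6 and rga-8, znf-474 and mrck-1 (higher in replicate 1) and near gob-1, Y39A1C.1 and pash-1 (higher in replicate 2). The hst-6 and rga-8 peak ranked 830 in replicate 1 and 17842 in replicate 2, and the gob-1 peak ranked 13678 in replicate 1 and 817 in replicate 2. The peak near mrck-1 ranked 220 and 9099 at 50% reciprocal overlap, but 220 and 38 when any overlapping entry was accepted.

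The mitochondrial genome separated the replicates. It held 13 entries in the list of replicate 2, the highest with rank 2 and a signal value of 479.7, but 1 entry in the list of replicate 1, with rank 348 and a signal value of 69.0. In the pooled list, 5 of the 20 strongest entries were mitochondrial, near ND1, COX3 and further mitochondrial genes. None of these 5 overlapped an entry of replicate 1.

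**Figure D1:**
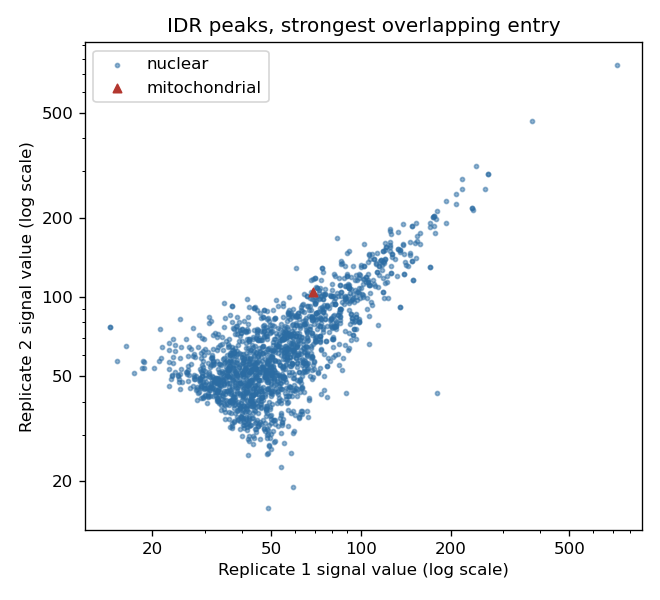
Signal value of each IDR peak in replicate 1 (x, log scale) and replicate 2 (y, log scale), taken from the strongest overlapping entry in each list, each on its list's own scale, for nuclear peaks (blue circles) and mitochondrial peaks (red triangle). Of the 10 mitochondrial peaks only the 1 that overlapped an entry of replicate 1 is drawn, and the strongest peak, at 720.3 and 761.5, lies at the upper right.

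CEH-14-GFP peaks concentrated at transcript starts and upstream of genes. Of the 1681 summits, 1375 (81.8%) lay within 1000 bases of an annotated transcript start, against 54.01 ± 1.18% (SD over 1000 random placements on the same chromosome). No placement reached the observed share (one-sided permutation p = 0.001, the smallest these placements can give). The median distance from a summit to the nearest start was 195 bases. For protein-coding genes alone the share was 62.998% against 40.8%. Many worm starts are annotated at trans-splice sites, so that distances are to annotated rather than to initiation sites.

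Sequence upstream of genes and non-coding exons held more summits than random placement gave, and coding exons and introns held fewer. Upstream sequence (1000 bases) held 805 summits (47.9%, against 16.16 ± 0.903% placed), and exons of non-coding genes held 254 (15.1%, against 3.27 ± 0.424%). Coding exons held 28 (1.67%, against 24.8 ± 1.06%), introns 326 (19.4%, against 34.4 ± 1.18%) and other intergenic sequence 201 (11.96%, against 16.6 ± 0.925%). Each of these 5 classes differed from placement with a two-sided permutation p of 0.002, the smallest these placements can give. Untranslated regions held 67 summits (3.99%, against 4.79 ± 0.509%; permutation p = 0.126), and this share did not pass the threshold. Among the 840 strongest peaks, it was 2.74% (permutation p = 0.00999).

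**Figure D2:**
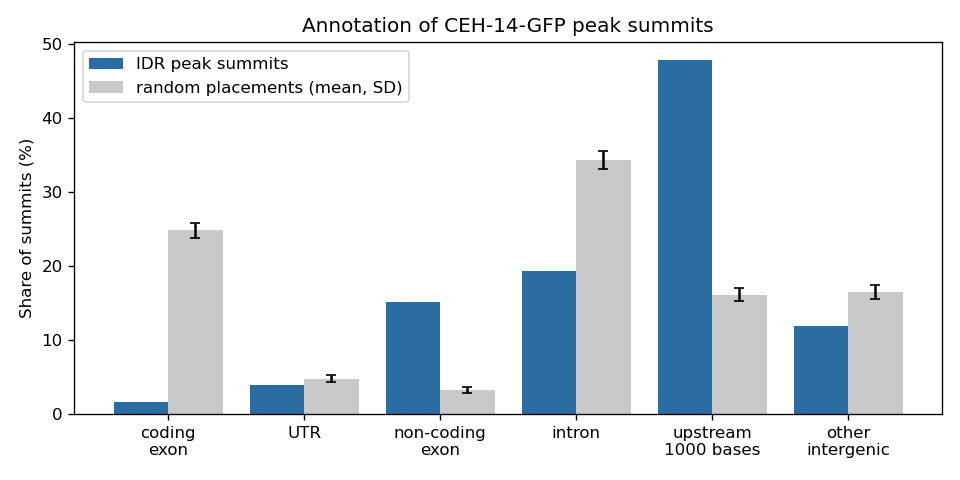
Share of the 1681 IDR peak summits (blue bars) in each annotation class, in percent, beside the mean of 1000 random placements on the same chromosome (grey bars, SD as error bars). Upstream sequence holds 47.9% of summits against 16.16%, and coding exons 1.67% against 24.8%.

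The middle parts of the autosomes held more peaks than their length gives. Of the 1347 autosomal summits, 788 (58.5%, Wilson 95% interval 55.8 to 61.1%) lay in the outer parts of the autosomes, which hold 66.7% of their sequence (exact binomial p = 4.68e-10, two-sided). Chromosome X held 324 of 1671 nuclear summits (19.4%, Wilson 95% interval 17.6 to 21.4%) against 17.7% of the sequence, a difference that did not pass the threshold (exact binomial p = 0.0675). With replicate 2 left out, the X share was 20.1% (exact binomial p = 0.0115).

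Ribosomal protein, heat shock and panneuronal genes held peaks more often than other genes, and chemoreceptor genes held them less often. Of 19985 protein-coding genes, 1362 (6.82%) had a summit within 1000 bases of a start. Ribosomal protein genes had one at 24 of 78 (30.8%, Wilson 95% interval 21.6 to 41.7%; Fisher's exact test with Benjamini-Hochberg adjustment over 29 lists, adjusted exact p = 2.65e-09). The odds ratio was 6.17, against 3.29 when each summit was given to its single nearest start and 2.56 among genes with a pooled entry, both past the threshold. The ribosomal protein genes were led by rpl-3, rps-24, rpl-15, rpl-35 and rps-28, whose peaks ranked 13, 24, 33, 48 and 53. Heat shock and proteostasis genes had one at 7 of 17 (41.2%, interval 21.6 to 63.99%, adjusted exact p = 0.000516). The strongest of these were at hsp-1, an Hsp70-family gene, with rank 103, hsp-60 with rank 173, hsp-90 with rank 230, hsp-3 with rank 555 and hsp-110 with rank 1223. The stress-induced small heat shock genes hsp-16.1, hsp-16.2, hsp-16.41 and hsp-16.48 had none. When each summit was given to its single nearest start, the heat shock list no longer passed the threshold (odds ratio 3.91, adjusted exact p = 0.152, against 9.62 by the window).

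Panneuronal genes, which neurons of all kinds express, had a peak at 10 of 25 (40%, interval 23.4 to 59.3%, adjusted exact p = 2.56e-05). The strongest were at syd-2, a synapse scaffold gene, with rank 297 and a signal value of 156.4, rgef-1 with rank 415 and 135.3, egl-21, a neuropeptide processing gene, with rank 550 and 122.8, rab-3, a synaptic vesicle gene, with rank 1095 and 90.7, and ehs-1 with rank 1227 and 86.1. The odds ratio of the panneuronal list was 9.18, against 19.2 with the single nearest start, 16.3 with 5000 bases upstream or the gene body and 4.005 among genes with a pooled entry, all past the threshold (adjusted exact p = 0.0104 for the last). Among the 840 strongest peaks the list no longer passed (odds ratio 3.52, adjusted exact p = 0.473). A gene with more annotated starts, or a longer gene in the gene-body setting, has more room for a summit. Neither the number of starts nor gene length was adjusted for in any of these settings. Chemoreceptor genes had a peak at 7 of 1275 (0.549%, interval 0.266 to 1.13%, adjusted exact p = 3.64e-29), the strongest at sre-23 with rank 37, sre-1, srh-269, str-12 and srh-89. These 4 lists were the only ones of the 29 that passed the threshold in IDR peaks.

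Lists tied to CEH-14 itself did not pass. The LIM homeobox genes ceh-14, lin-11, mec-3, ttx-3, lim-4, lim-6 and lim-7 had 0 peaks, as did the 6 Hox genes, the 13 proneural bHLH genes, the 20 phasmid and tail sensory neuron genes and the 17 genes of neurotransmitter synthesis and transport. These counts are for IDR summits within 1000 bases of a start. Chromatin came from whole embryos, so the counts cannot tell genes bound in only a few cells from genes not bound. Among the strongest entries of replicate 2 alone, 1 of 6 Hox genes and 1 of 17 neurotransmitter genes had one. The LIM homeobox, proneural bHLH and phasmid lists stayed at 0, and none of these lists passed. Homeobox genes as a whole had a peak at 4 of 100 (4%, against 6.83% of other genes, adjusted exact p = 0.625): unc-62, with rank 346, ceh-58, ceh-38 and ceh-39. The direction turned, without passing the threshold, when each summit was given to its single nearest start (12 of 100, against 7.29%) and with 5000 bases upstream or the gene body (17 of 100, against 13.7%). Of 20 AFD genes, cmk-1, which encodes a calmodulin-dependent kinase, had the rank 323 and tax-6, which encodes calcineurin, the rank 837 (10%, adjusted exact p = 0.888). The AFD genes gcy-8, gcy-18 and ttx-1 had no entry within 1000 bases in any list. Others, such as ttx-7, tbx-2 and tax-4, had pooled entries below the IDR peaks, with ranks 3364, 3774 and 4699. Of 14 ALA genes, sax-7 had a peak (7.14%, adjusted exact p = 1), and of 16 BDU and posterior interneuron genes zig-1 and ser-2 did (12.5%, adjusted exact p = 0.618). With replicate 1 left out the BDU list had 4 of 16 (adjusted exact p = 0.105), and without peaks near tRNA, snoRNA or snRNA genes it had 1 of 16 (adjusted exact p = 1). With so few members, the upper interval limit for the 7 LIM homeobox genes is 35.4%, so that a share well above that of other genes was not excluded. The gene ceh-14 counts as a member without a peak in the LIM homeobox, homeobox, AFD, ALA, BDU and phasmid lists, although it lies in a stretch without any entry, where it is not known whether peaks could be called.

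The remaining lists did not pass the threshold either. Wnt pathway genes had a peak at 5 of 27 (18.5%, adjusted exact p = 0.149), at mig-5, vang-1, lin-17, wrm-1 and lit-1. Body muscle genes had one at 4 of 31 (adjusted exact p = 0.442), at unc-112, unc-60, mup-2 and unc-22, and histone genes at 6 of 50 (adjusted exact p = 0.442), led by his-67 and his-68, which share a peak. Axon guidance and adhesion genes had one at 3 of 36 (unc-76, sax-7 and fmi-1, adjusted exact p = 0.926), and ciliary genes at 2 of 35 (daf-19 with rank 219 and dyf-11, adjusted exact p = 1). Collagen genes had one at 4 of 156 (adjusted exact p = 0.149), led by col-85, and nuclear hormone receptor genes at 9 of 269 (adjusted exact p = 0.116), led by nhr-255. Both lists passed the threshold, with fewer peaks than other genes, in some settings. Collagen genes did so among genes with a pooled entry (odds ratio 0.211, adjusted exact p = 0.00286), but had an odds ratio of 1.17 with replicate 2 left out (adjusted exact p = 0.883). In pooled entries ranked 1682 to 5000, just below the IDR peaks, collagen genes had one more often than other genes (46 of 156, 29.5%, against 9.92%). Nuclear hormone receptor genes did so at 2000 bases (odds ratio 0.438, adjusted exact p = 0.0137) and with 5000 bases upstream or the gene body (odds ratio 0.421, adjusted exact p = 0.00115). With 5000 bases upstream or the gene body, Wnt pathway genes passed with more peaks than other genes (9 of 27, adjusted exact p = 0.0280), and neuropeptide-like protein genes (2 of 71, 0.0241) and insulin-like genes (0 of 38, 0.0280) passed with fewer. Neuropeptide-like protein genes had one at 2 of 71 (nlp-4 and nlp-82, adjusted exact p = 0.576), FMRFamide-like genes at 1 of 31 (flp-23, adjusted exact p = 0.926) and germline genes at 1 of 36 (mex-1 with rank 34, adjusted exact p = 0.828). No peak was met at the 38 insulin-like genes (adjusted exact p = 0.400 by the exact test), 32 epidermis genes (0.442), 31 sperm major protein genes (0.601), 25 intestine genes (0.703), 18 pharynx genes (0.888) or 13 glia genes (adjusted exact p = 1).

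**Figure D3:**
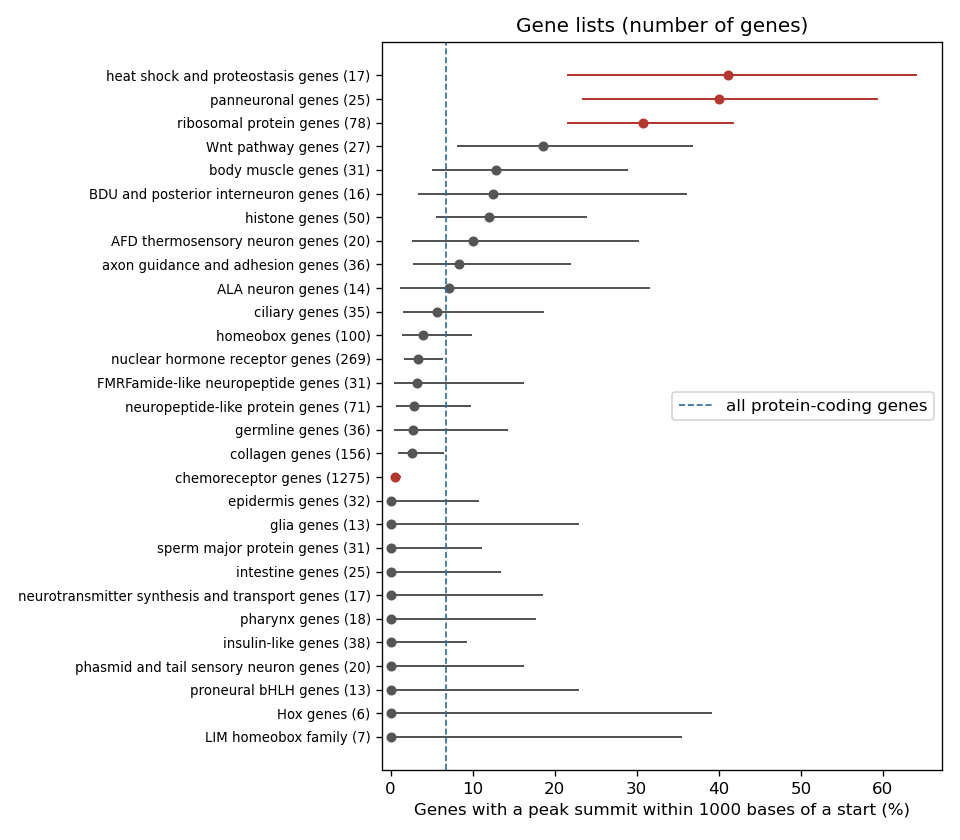
Percent of the protein-coding genes of each list with an IDR peak summit within 1000 bases of a transcript start (x), with Wilson 95% intervals, for 29 lists (y, number of genes in brackets). Red marks the 4 lists past the adjusted threshold of 0.05, and the dashed line marks the 6.82% of all protein-coding genes; heat shock, panneuronal and ribosomal protein genes lie above it and chemoreceptor genes below.

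TAATTA, a core that LIM homeodomain proteins bind, was not detectably more frequent at the summits than beside them, while GA-rich and GC-rich hexamers were raised. TAATTA lay within 50 bases of the summit in 99 of 1681 peaks (5.89%) and in the flanks of 91 (5.41%), a ratio of 1.09 (exact McNemar test, adjusted exact p = 0.688). With replicate 2 left out the ratio was 1.42 (adjusted exact p = 0.0452). The summits were richer in GC than the flanks (47.8 ± 8.73% against 36.1 ± 7.85%, mean and SD over peaks), and of the 36 hexamers made of A and T alone 34 were lowered. TAATTA had the highest ratio of these 36, and ATTAAT (ratio 0.877), named after its value was seen, was the only other that was not lowered. TAATTG was met in 117 summits and 136 flanks (ratio 0.860, adjusted exact p = 0.326). GAGAGA was met in 432 summits (25.7%) and 126 flanks (7.50%), a ratio of 3.43 (adjusted exact p = 3.78e-43), the smallest p of the raised hexamers. AGAGAG (ratio 3.50), GAGCGC (ratio 8.33) and AGCGCG (ratio 11.7) followed; these hexamers were named after their values were seen. The GATA-type hexamers TGATAA (ratio 0.277, adjusted exact p = 7.61e-15) and GATAAG (ratio 0.435, adjusted exact p = 0.000728) were lowered, and the E-box CACGTG was even (ratio 1.03, adjusted exact p = 1). The lowering was not particular to GATA-type sites: 174 of 192 hexamers with 1 G or C base, as TGATAA has, and 196 of 492 with 2, as GATAAG has, were lowered. Of 2080 hexamers, 628 were raised and 444 lowered.

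**Figure D4:**
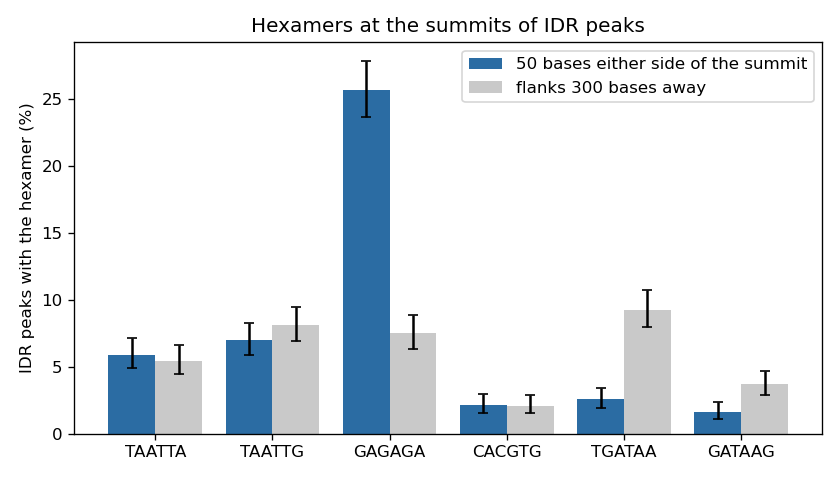
Percent of the 1681 IDR peaks with each of 6 fixed hexamers (x) within 50 bases of the summit (blue) and in flanks of about the same total length centred 300 bases away (grey), with Wilson 95% intervals. GAGAGA stands at 25.7% against 7.50%, TAATTA at 5.89% against 5.41%.

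Peaks near transcript starts were stronger than others, and peaks with TAATTA were not detectably stronger or weaker. The median signal value was 105.1 for the 1375 peaks within 1000 bases of a start and 92.8 for the 306 others, a difference of 12.3 (two-sided permutation p = 9.0e-05). With a window of 2000 bases the difference was 7.98 (permutation p = 0.0551). The 99 peaks with TAATTA had a median of 101.9 (bootstrap 95% interval 90.9 to 113.2) and the 1582 without it 102.9 (100.7 to 105.0), a difference of -1.01 (permutation p = 0.841). Among the strongest entries of replicate 1 alone the difference was -4.67 (permutation p = 0.0384).

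No entry of any list lay within 5000 bases of ceh-14, the tagged gene (WBGene00000438, X, 7527769 to 7532732, minus strand). In the pooled list the nearest entries ended at 7511329 and began at 7562599, leaving 51269 bases without an entry, where 10 protein-coding genes start. Of 3910 gaps between entries on X in that list, 6 were as long, and the median gap was 2680 bases. The empty stretch was 51168 bases in replicate 1 and 58293 bases in replicate 2. The labels describe an insertion targeting ceh-14, and whether it bears on the empty stretch was not tested. Whether entries could be called in this stretch, or whether it was left out before the lists were made, is not given in the sources used here, so the absence of entries at ceh-14 is not a measured absence of CEH-14.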

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

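The pooled entries below the IDR peaks were split by rank only after the first results were seen, and the comparison with other A and T hexamers below was also chosen after the result was seen.

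In the 20085 entries of the pooled list below the IDR peaks, planned only as a background for the IDR summits, the LIM homeodomain core TAATTA was met within 50 bases of the summit in 1781 (8.87%) and in the flanks of 1007 (5.01%), a ratio of 1.77 (exact McNemar test, adjusted exact p = 1.67e-50). No other hexamer was raised with a smaller p there. In entries 1682 to 5000 alone, TAATTA stood at place 135 by p among the raised hexamers, and GAGAGA (ratio 2.36) stood at place 1. TAATTA stood at place 2, 1 and 1 in the later ranges of rank, and at place 8 in the entries of replicate 1 ranked below 1681. By rank, the ratio was 1.68 for entries 1682 to 5000, 1.82 for 5001 to 10000, 1.96 for 10001 to 15000 and 1.64 for 15001 to 21766, against 1.09 in the IDR peaks. The related TAATTG had a ratio of 1.06 (adjusted exact p = 0.0958). Compared with pooled entries outside them, the IDR peaks had TAATTA less often, with a ratio of 0.658 (Fisher's exact test, adjusted p = 4.28e-05). That was not particular to TAATTA: the IDR summits had 47.8% GC against 40.2% in the entries below them, and 12 of the 13 other hexamers of 3 A and 3 T bases had ratios at or below 0.658, with a median of 0.494.

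Hexamers of the same bases were not raised as much as TAATTA within these entries. Of the 13 others of 3 A and 3 T bases, 0 had a ratio at or above its own. Their ratios ran from 0.750 for AAATTT to 1.25 for TATATA and 1.46 for ATTAAT. This comparison was chosen after the result of TAATTA was seen, so it cannot exclude a part of base composition. Nearness to annotated starts does not account for the raised TAATTA, since among the 7932 entries over 1000 bases from every annotated start the ratio was 1.82 (exact McNemar p = 7.82e-23). Many starts are annotated at trans-splice sites, so this distance cannot exclude promoter sequence farther away. The raised TAATTA was not in 1 replicate alone: entries ranked below 1681 had a ratio of 1.76 in replicate 2 and 1.49 in replicate 1, the lower of both (exact McNemar p = 7.64e-25). In the IDR peaks, too, no other hexamer of A and T alone had a higher ratio than TAATTA, so the contrast of 1.77 with 1.09 was not separated from the GC content of the IDR summits. The ratio did not fall steadily with rank in these entries, which include background regions. A candidate explanation is that CEH-14 bound some of the weaker entries through this core. That was not tested against other homeodomain proteins, many of which share the core, so it stays open whether the tagged protein or sites open to any such protein set it, and no biological explanation was tested.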

How the results depend on the processing

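Settings that leave out mitochondrial peaks or peaks near tRNA, snoRNA and snRNA genes, and the ranges of rank, were chosen after the data were seen. Of 537 alternative values, 503 were on the same side of the threshold, in the same direction where past it, or were counts within 1.5 times the main count. Results not past the threshold could change direction within these. The share of summits near starts of any gene was 79.8 to 85.7% in settings that kept the window of 1000 bases. No paired analysis was possible because the series holds 1 group. IDR values are not given, so the stronger 840 peaks by signal value stood for a stricter threshold. The strongest pooled entries are the IDR peaks themselves, so that setting changes nothing. Its values are counted among the 503 although they could not differ. The cause of the changes below was not tested.

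Against pooled entries outside the IDR peaks, the TAATTA ratio was below 1, at 0.658 (adjusted exact p = 4.28e-05), and that of TAATTG was 0.795 (0.0234). By rank the TAATTA ratio was 1.68, 1.82, 1.96 and 1.64, GAGAGA fell to 1.12 in the last range (adjusted exact p = 0.267), and 8, 10, 3 and 1 lists passed. Among the stronger 840 peaks, untranslated regions held 2.74% and the panneuronal odds ratio was 3.52. With overlapping entries merged the X share was 19.7% (exact p = 0.0409). Leaving out a replicate gave X shares of 18.9 to 20.1%, TAATTA ratios of 1.23 to 1.42 and TAATTA strength differences of -4.67 to 0.169. The strength difference by position was 7.98 at 2000 bases, the heat shock odds ratio was 3.91 with the single nearest start, 8 lists passed with 5000 bases upstream or the gene body (Wnt pathway, neuropeptide-like protein, insulin-like and nuclear hormone receptor genes in addition), and 253 hexamers were lowered at 25 bases. The replicates' shared share was 71.3% at 1 base of overlap, 47.9% with summits within 50 bases, 64.2% for the 500 strongest and 62.2% for the 3000 strongest entries.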

Other observations

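The distance of 200 bases to tRNA, snoRNA, snRNA and miRNA genes and the gene lists in ranges of rank were chosen only after the peaks had been seen.

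Genes for tRNAs and snoRNAs held many of the peaks. Of 612 nuclear tRNA genes, 152 (24.8%) had an IDR summit within 200 bases, and of 346 snoRNA genes 53 did (15.3%). The shares were 7.75% for snRNA genes and 3.07% for miRNA genes, and no test compared the classes. In all, 148 summits lay near tRNA genes, against 4.81 ± 2.25 (SD) placed at random on the chromosome, and 53 near snoRNA genes, against 3.23 ± 1.81 (permutation p = 0.001 for each, the smallest possible, adjusted p = 0.00133 over 4 gene classes). The other classes were above placement as well, snRNA genes with 13 summits against 1.02 ± 1.01 (permutation p = 0.001, the smallest possible) and miRNA genes with 8 against 2.07 ± 1.46 (permutation p = 0.002). Of the 15 nuclear peaks among the 20 strongest, 5 lay near snoRNA genes, W03C9.9, ZK994.7, C51F7.3 with C51F7.4, T03F7.8 and T06C12.16, which were named after their values were seen. The 4 lists past the threshold did not rest on these peaks: without the 214 peaks near tRNA, snoRNA or snRNA genes, ribosomal protein genes had a peak at 23 of 78 (adjusted exact p = 3.96e-09) and panneuronal genes at 10 of 25 (adjusted exact p = 1.33e-05), and heat shock and chemoreceptor genes passed as well. With these peaks left out 6 lists passed, since collagen genes (2 of 156, adjusted exact p = 0.0259) and nuclear hormone receptor genes (7 of 269, adjusted exact p = 0.0374) then had peaks less often than other genes.

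Below the IDR peaks further lists passed the threshold. In entries ranked 1682 to 5000 of the pooled list, collagen genes had an entry at 46 of 156 (29.5%, adjusted exact p = 1.54e-10), Hox genes at 4 of 6 (adjusted exact p = 0.00755), body muscle genes at 9 of 31 (adjusted exact p = 0.0112), BDU and posterior interneuron genes at 6 of 16 (adjusted exact p = 0.0123) and axon guidance and adhesion genes at 10 of 36 (adjusted exact p = 0.0111). Ribosomal protein genes (30 of 78, adjusted exact p = 2.67e-10) and panneuronal genes (11 of 25, adjusted exact p = 8.91e-05) passed there too, as in the IDR peaks. In entries ranked 5001 to 10000, homeobox genes had one at 28 of 100 (28.0%, adjusted exact p = 0.000495), against 12.57% of other genes. This was not particular to them: body muscle (38.7%), Wnt pathway (37.04%), axon guidance and adhesion (36.1%), panneuronal (32%), ciliary (31.4%), epidermis (31.2%), collagen (26.3%) and ribosomal protein genes (25.6%) also passed with more entries than other genes. In the IDR peaks, a smaller set, homeobox genes had a peak at 4 of 100 against 6.83% of other genes, a direction that turned with the single nearest start, and the difference between the ranges was not tested. Chemoreceptor genes had entries less often than other genes in each range of rank.

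Recovery of tRNA genes was weighed against 2 technical explanations. Gene-dense sequence near starts does not account for it: with summits placed within 1000 bases of protein-coding starts, 1000 placements gave at most 11 near tRNA genes, against 148 (permutation p = 0.001, the smallest possible). DNA that is highly transcribed may be recovered without binding of the tagged protein, as tRNA, snoRNA, ribosomal protein and heat shock genes would be. That could not be told apart from binding for the 8.86% of nuclear summits near tRNA genes, since no list from worms without the tag was analysed here.

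The GAGAGA at IDR summits was weighed likewise. Higher GC content there does not account for all of it, since among the 233 peaks with no more GC at the summit than in the flanks the ratio was 2.73 (exact McNemar p = 0.000106). Overlapping entries and runs of GAGAGAGA do not either. With entries merged and centres with GAGAGAGA left out, the ratio was 2.98 over 1482 peaks (exact McNemar p = 1.38e-26). Shorter or interrupted GA repeats stayed in, so this filter cannot exclude them. Which protein, if any, binds these sites was not tested.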
